A study of Mus musculus with 9 samples.

How the data were processed

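RNA was measured in punches of the BNST, the NAc and the dStr taken from semi-frozen coronal mouse brain slices of 300 µm. Per the labels, total RNA was extracted with Stat-60, and 10 ng of it was labelled with biotin in a protocol with repeated amplification and hybridised to Affymetrix Mouse430_2 arrays. The values are linear probe-set summaries in units of intensity, as deposited by the authors in 1 table of 45037 probe sets and 9 arrays. The summarisation software and the scaling are not given in the sources used here. Every array had the same lowest value of 15, to which low signals had been set, and 2270 to 2698 probe sets per array stood at it. Array medians ran from 93.9 to 102, and the largest gap between them was 0.12 on the log2 scale, under the limit of 0.5 set for rescaling, so the deposited scaling was kept. With 9 arrays, the number of arrays limits the precision.

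Values were tested as log2(value + 16), so that folds of genes near the floor are smaller than ratios of their intensities. A fold against a region with all 3 arrays at the floor is given as a lower bound, computed from the intensities, and is not on the scale of the other folds. With 1 or 2 arrays at the floor the fold is that of the log2(value + 16) means. Of the probe sets, 34945 had 1 gene symbol, 932 several and 9160 none in the annotation table used, and 34741 symbols were matched by Entrez identifier to a current symbol, which changed 0 of them. A probe set was kept if at least 3 of the 9 arrays lay above the 40th percentile of their own array, which left 29293, control probe sets being left out. A gene was represented by its kept probe set with the highest mean over all arrays, which gave 14208 genes, 5897 of them with several kept probe sets. Probe sets with no or several symbols were left out of the gene tests. Of these, 5470 passed the filter, and they were tested apart.

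The arrays were grouped by region from the labels, with 3 per region. Each pair of regions was compared with limma 3.58.1 in R 4.3.3, by 1 linear model over the 9 arrays with a mean per region, which left 6 residual degrees of freedom, and an empirical Bayes moderated test. P-values were adjusted by Benjamini-Hochberg over all genes in each comparison, with a threshold of 0.05, and all tests were 2-sided. The moderated F test over the 3 regions was treated alike. A gene was called highest in a region if it passed in both comparisons with that region. Gene lists were tested with limma's camera with a preset correlation of 0.01, adjusted by Benjamini-Hochberg over the 25 lists, and again with an estimated correlation, with which 2 lists passed between BNST and NAc, 0 between BNST and dStr and 1 between NAc and dStr, and with which 6, 7 and 4 lists had an unadjusted p under 0.05. The lists held 592 symbols, of which 457 were tested, 4 of them under a newer symbol. Within each list the gene p-values were also adjusted over the list alone. An unadjusted p under 0.05 was reached by 1796 genes between BNST and NAc, 4118 between BNST and dStr and 1860 between NAc and dStr.

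The regions, tests, filter, thresholds, gene lists, most alternatives and the rule for naming genes were set before the data were examined. By that rule the text draws on the 10 genes with the largest absolute difference per comparison and direction, among those that passed, whose arrays did not overlap and whose mean in the higher region exceeded the median of all probe sets, on up to 4 passing members of each list per comparison and direction, and on the 10 genes per region with the largest smaller difference among those highest in it. Of the 238 named results, 99 had several kept probe sets, and in 13 of them 1 or more of these went the other way. Genes without an established name were skipped. Genes of a list outside this rule, given where the members that passed or did not pass are listed, were chosen after their values were seen.

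Alternatives were quantile normalisation, centring each array on its median, no filter, a filter at the 60th percentile, the mean of a gene's probe sets, a trend and robust prior, a block on replicate number, pseudocounts of 1 and 64, leaving out each array in turn, using the arrays of the pair alone, and an absolute log2 difference of at least 1. A housekeeping covariate, leaving out BNST 1 and NAc 1 together, and probe sets with unsuffixed names alone were added after the data were seen. The procedure was tested on simulated data of 14208 genes with 3 arrays per region. The changed genes were drawn from those with a mean above the median, and the noise was independent between genes and arrays. The rates therefore do not cover dimmer genes or the correlated spread of these arrays. Camera called 1 list in the simulated data between BNST and dStr and 0 in the other comparisons. A log2 change of 1 was recovered in 63% of changed genes between BNST and NAc, 67% between BNST and dStr and 59% between NAc and dStr, a change of 2 in 94%, 94% and 96%, with 12, 11 and 7 false calls.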

Results

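Gene expression was compared between 3 regions of the mouse forebrain. They were the bed nucleus of the stria terminalis (BNST), a limbic nucleus of the extended amygdala, the nucleus accumbens (NAc), the ventral part of the striatum, and the dorsal striatum (dStr). Each region had 3 samples, given in the labels as biological replicates, and each sample was read on 1 Affymetrix Mouse430_2 array. The median probe-set intensity of the 9 arrays lay between 93.9 and 102, and between 2270 and 2698 of the 45037 probe sets on an array stood at a common floor of 15. A total of 14208 genes were tested, of which 1461 differed among the regions (limma F test, adjusted p under 0.05). That count was 893 without BNST 2, 740 without BNST 3, 771 without dStr 1, 886 without dStr 2 and 779 without dStr 3. Whether the replicates came from separate animals bounds what the p-values measure.

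The 3 dStr arrays resembled one another, whereas BNST 1 and NAc 1 stood apart from the other arrays of their regions. BNST 2 and BNST 3 correlated at r = 0.981 across genes, and NAc 2 and NAc 3 at 0.964. Pearson's r across genes, which are not independent replicates, ran from 0.909 to 0.981 between arrays of 1 region and from 0.843 to 0.965 between arrays of different regions. BNST 1 correlated most closely with NAc 3 (r = 0.965 across genes), above its r of 0.934 with BNST 2 and 0.948 with BNST 3. The first principal component held 49.7% of the variance and ran from BNST through NAc to dStr, with BNST 1 at -12.6 next to NAc 1 at -10.4. The second component held 20.3% and parted NAc 1 at -37.9 from BNST 1 at 27.5 and NAc 3 at 22.7. The mean of 116 ribosomal protein and respiratory chain genes was lowest on BNST 2 (10.1 on the log2 scale) and NAc 1 (10.2) and highest on NAc 3 (10.9).

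**Figure D1:**
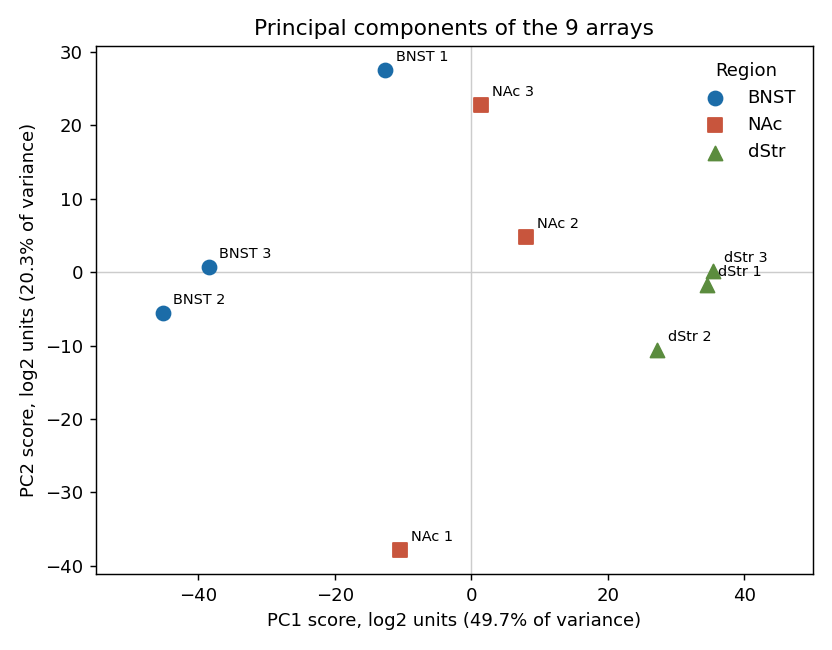
Principal component scores of the 9 arrays over all tested genes, with the first component (49.7% of the variance) on the horizontal axis, the second (20.3%) on the vertical axis, and 1 point per array in its region's colour. The 3 dStr arrays group between 27.2 and 35.5 on the first component, while NAc 1 (-37.9) and BNST 1 (27.5) stand apart on the second.

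BNST differed from dStr through higher levels of several peptide and ependymal genes, some of them near the array floor in dStr, and through lower levels of striatal projection neuron genes. Tac2, which encodes the neurokinin B precursor, averaged 964 ± 290 (SD, n = 3 arrays) in BNST and 25.1 ± 3.28 in dStr, a log2 difference of 4.54 (SE 0.27, adjusted p = 2.9e-05). Crh, the corticotropin-releasing hormone gene, averaged 476 ± 172 against 19.2 ± 6.87, which was 13.5-fold higher in BNST. Calb2 (calretinin) was 15.6-fold higher, Dlk1 13.5-fold (2 of the 3 dStr arrays at the floor), and Baiap3, which acts in dense-core vesicle release, 11.5-fold (1870 ± 52.5 against 149 ± 30.1). In the other direction, Scn4b, a sodium channel subunit gene of striatal projection neurons, averaged 290 ± 256 in BNST and 3340 ± 326 in dStr, a log2 difference of -3.80 (SE 0.53, adjusted p = 0.0012). Every gene given with a fold, in this and the other comparisons, had all 3 arrays of the higher region above all 3 arrays of the lower one.

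Of the 14208 genes, 2027 passed the test between BNST and dStr, 702 of them higher and 1325 lower in BNST. An absolute log2 difference of at least 1 was present in 866 of them, 267 higher and 599 lower. The arrays did not overlap for 36.4% of genes, against an average of 10% over all splits of 3 against 3. Wdr6 (9.52-fold), Cartpt (8.21-fold), the neurotensin gene Nts (7.05-fold) and the kainate receptor gene Grik1 (5.8-fold) were among the genes higher in BNST. Tmem212 was at least 38.7-fold and the homeobox gene Otx2 at least 18-fold higher, both with all dStr arrays at the floor. The formin gene Inf2 (10.9-fold), Gprin3 (10.4-fold, with 2 of the 3 BNST arrays at the floor), Rasgrp2, an activator of Rap GTPases (10.1-fold), the actin-binding gene Nexn (10.1-fold) and Mme, which encodes the peptidase neprilysin (9.18-fold), were lower in BNST.

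The fixed lists placed these genes in groups. In the medium spiny neuron list 28 of 31 measured members were lower in BNST and none higher (29 lower adjusted over the list alone), with a mean log2 difference of -2.08 (camera adjusted p = 8.22e-22; adjusted p = 0.133 with an estimated correlation). The dopamine-regulated phosphatase inhibitor gene Ppp1r1b (8.29-fold), Rasd2 (8.73-fold), the orphan receptor gene Gpr6 (8.46-fold), Drd1 (6.79-fold), Drd2 (6.33-fold) and Rgs9 (6.02-fold) were all lower. The exceptions that did not pass were Pdyn at -0.17, Isl1 at 0.03 and Ebf1 at -0.86. Of 44 metabotropic and cyclic nucleotide signalling genes, 24 were lower, among them the phosphodiesterase gene Pde10a (6.82-fold), and 5 higher, among them Pde1a (3.65-fold) and Gnas (2.52-fold), with 27 and 7 adjusted over the list alone. Their mean was -0.80 (adjusted p = 3.11e-05, and 0.326 with an estimated correlation). Pde10a, Ppp1r1b, Rgs9 and Gng7, among others, are on this list and on the medium spiny neuron list, so these list results are not independent. Voltage-gated potassium channel genes had 16 of 30 lower, including Kcnq3 (5.9-fold) and Kcna4 (4.99-fold), and 5 higher, including Kcnd3 (1.87-fold). Adjusted over the list alone these were 18 and 5, with a mean of -0.54 (adjusted p = 0.000915; adjusted p = 0.272 with an estimated correlation).

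Some neuropeptide and neuropeptide receptor genes were higher in BNST than in dStr, while most members of both lists did not pass. Of 32 neuropeptide and hormone genes 6 were higher (Tac2, Crh, Cartpt, Nts, Pnoc and Ecel1) and Tac1 (3.61-fold) and Penk (2.32-fold) lower, or 8 and 2 adjusted over the list alone. The list mean was 0.49 and its median 0.11 (adjusted p = 0.00303, and 0.326 with an estimated correlation). Of 25 neuropeptide receptor genes 5 were higher and 1 lower (8 and 1 adjusted over the list alone). Their mean was 0.41 and their median 0.21 (adjusted p = 0.000463, and 0.059 with an estimated correlation). Adcyap1r1, the receptor gene for the peptide PACAP, was 2.82-fold higher, although its other kept probe set went the opposite way. In the ventral striatum list 10 of 15 genes were higher in BNST and none lower (11 higher and 1 lower adjusted over the list alone), with a mean of 1.66 (adjusted p = 1.06e-08; adjusted p = 0.059 with an estimated correlation). Cartpt, Nts, Tac2, Calcr and Trhr, among others, are also on the neuropeptide or receptor list, and Dlk1 is also on the imprinted list. These list results are therefore not independent. The thalamus and habenula list, which shares Tac2 and Calb2 with other lists, had 5 of 18 higher, including the vesicular glutamate transporter gene Slc17a6 (4.32-fold) and Prkcd (2.26-fold), and 1 lower. The counts were the same adjusted over the list alone. The mean was 0.58 and the median 0.24 (adjusted p = 0.00442, and 0.133 with an estimated correlation).

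Imprinted genes were higher in BNST for 13 of 27 members and lower for 3 (16 and 3 adjusted over the list alone). Asb4 (6.66-fold), Magel2 (5.8-fold), Grb10 (a log2 difference of 1.49) and Ddc (1.48) were higher, and Cobl (2.99-fold) and Ppp1r9a (2.08-fold) lower. The mean of the list was 0.78 (adjusted p = 1.39e-07; adjusted p = 0.0739 with an estimated correlation). Astrocyte genes had 7 of 22 higher and none lower (9 and 0 adjusted over the list alone), among them Gfap (3.44-fold), Mlc1 (2.96-fold) and Agt (2.83-fold), with a mean of 0.58 (adjusted p = 9.61e-07; adjusted p = 0.059 with an estimated correlation). The ependyma and choroid plexus list had 7 of 16 higher and none lower, over all genes and adjusted over the list alone, with a mean of 1.28 and a median of 0.38 (adjusted p = 5.77e-08; adjusted p = 0.0662 with an estimated correlation). Microglia genes were lower for 6 of 14 members (11 adjusted over the list alone), among them Tmem119 (1.53-fold), with a mean of -0.59 (adjusted p = 5.59e-05; adjusted p = 0.225 with an estimated correlation). Immediate early genes, which respond to neuronal activity, were lower for 9 of 25 members and higher for none, or 12 lower and 1 higher adjusted over the list alone. Egr3 (5.35-fold), Homer1 (4.9-fold) and Egr4 (3.68-fold) had the largest differences of these 9, and the mean was -0.78 (adjusted p = 0.000595; adjusted p = 0.272 with an estimated correlation).

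Quantile normalisation, in place of the deposited scaling, moved the share of genes higher in BNST than in dStr from 34.6% to 52.1% (1266 higher and 1164 lower), and it shifted the median of all genes by 0.117 on the log2 scale. The list tests set each list against the remaining genes and so are relative to that shift, and all 32 list means that passed in the 3 comparisons kept their sign under both other scalings. The 2027 genes became 1193 without BNST 2, 1112 without BNST 3, 1174 without dStr 1 and 1171 without dStr 3. Of 116 named calls in this comparison 24 ended when any 1 array was left out, 22 of them without dStr 3 and 21 without BNST 3, and none of those 24 is given above with a fold. Some of the 24 are counted in the lists above. For the microglia genes the highest adjusted p was 0.0536 for P2ry12 without dStr 3 and 0.11 for Tyrobp without dStr 1. For Ctss it was 0.122 without BNST 2. Among neuropeptide receptors it was 0.0559 for Npy2r without dStr 3, and 0.134 for Calcr and 0.159 for Trhr without dStr 1. For Oprm1, which was lower, it was 0.158 without BNST 3.

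**Figure D2:**
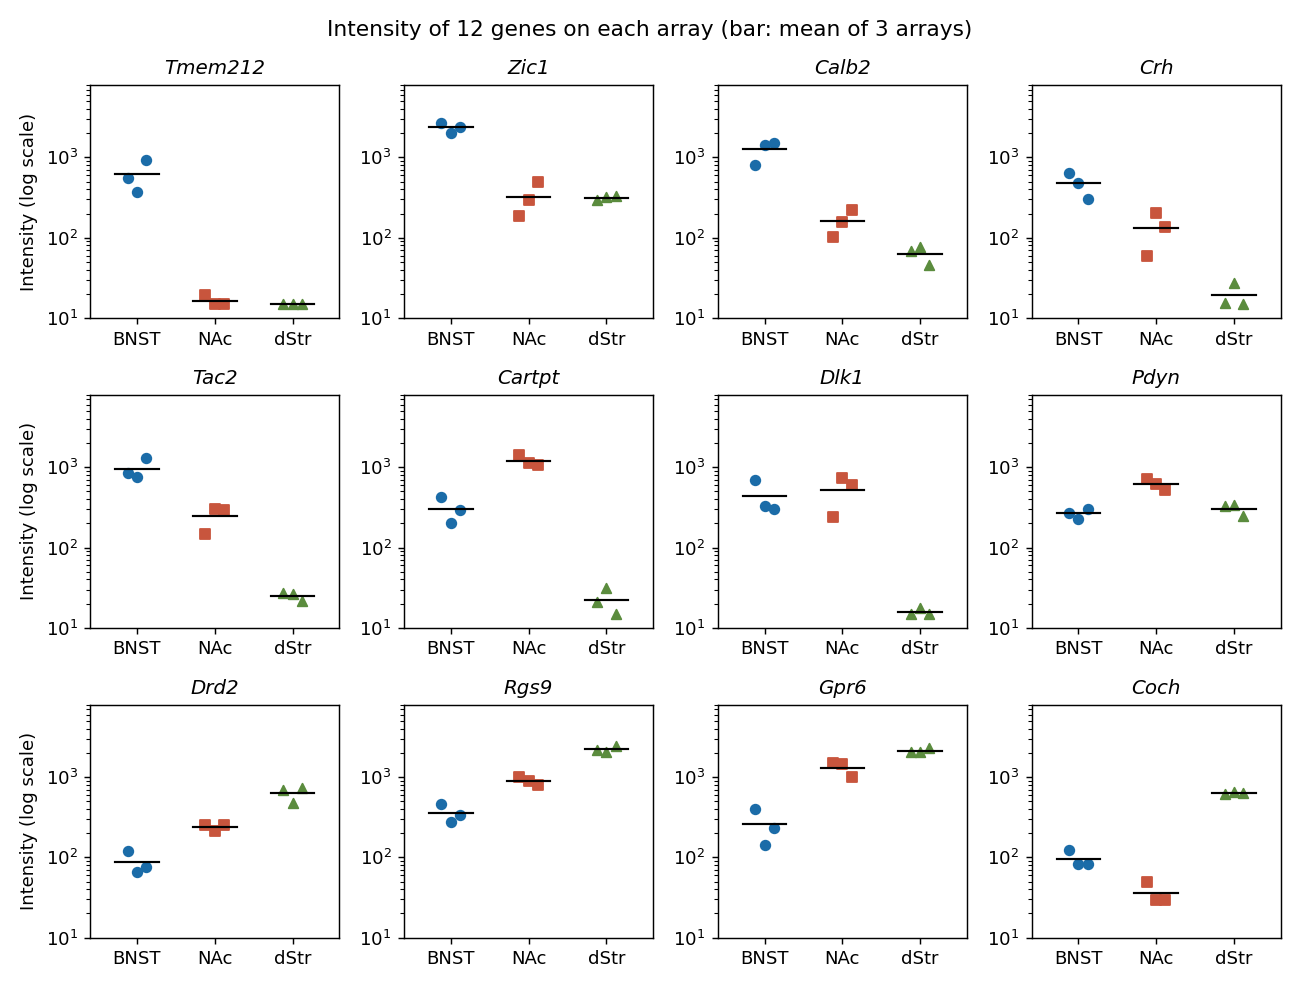
Intensity of 12 genes on each of the 9 arrays, on a log axis in array intensity units, with points for arrays and a bar for the mean of each region. Tac2, Crh and Calb2 are highest in BNST, Cartpt averages 1200 in NAc against 22.3 in dStr, and Coch averages 632 in dStr against 35.9 in NAc.

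Several ventral striatal genes were higher in NAc than in dStr. Cartpt, the gene of the CART peptide, averaged 1200 ± 186 (SD, n = 3 arrays) in NAc and 22.3 ± 8.16 in dStr, a log2 difference of 5.00 (SE 0.25, adjusted p = 1.1e-05). Dlk1 averaged 522 ± 252 against 15.8 ± 1.51, with 2 of the 3 dStr arrays at the floor, 15.4-fold higher in NAc, and Tac2 was 6.15-fold higher. Wfs1, the gene mutated in Wolfram syndrome, averaged 2650 ± 280 against 546 ± 77.3, 4.75-fold higher. Coch, which encodes cochlin, had the largest difference the other way, at 35.9 ± 11.2 in NAc and 632 ± 17.4 in dStr, a log2 difference of -3.66 (SE 0.18, adjusted p = 1.1e-05).

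Between NAc and dStr 291 genes passed, 135 higher and 156 lower in NAc, and 175 of them differed by at least 1 on the log2 scale (75 higher and 100 lower). The arrays did not overlap for 19.1% of genes, against an average of 10% over all splits. Baiap3 (5.75-fold), Cbln4, a secreted synaptic organiser (5.49-fold), the phosphodiesterase gene Pde1a (5.2-fold), the sodium-calcium exchanger gene Slc8a1 (4.42-fold) and Rasgrf2 (3.26-fold) were higher in NAc. Genes lower in NAc included Rasgrp2 (4.98-fold), the growth factor gene Fgf20 (4.75-fold), Abhd11os (4.69-fold), the semaphorin receptor gene Plxnd1 (4.43-fold), Fam241a (4.25-fold), Slc44a4 (4.11-fold) and the transcription factor gene Onecut2 (2.97-fold). Synpo2 was 7.3-fold lower, with its other kept probe set going the opposite way.

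The ventral striatum list had 9 of 15 members higher in NAc than in dStr and none lower (12 and 0 adjusted over the list alone), with a mean of 1.75 (camera adjusted p = 2.3e-16, and 0.0343 with an estimated correlation). Of the 31 medium spiny neuron genes 25 did not pass between NAc and dStr. Actn2 (3.37-fold), Rgs9 (2.44-fold), Drd2, Foxp1 and Syndig1l were lower and the prodynorphin gene Pdyn higher, or 11 lower and 1 higher adjusted over the list alone. The list mean was -0.71 (adjusted p = 3.18e-09; adjusted p = 0.532 with an estimated correlation). For Drd2, at 239 ± 20.1 in NAc and 633 ± 137 in dStr, the adjusted p was 0.01, and 0.0638 without dStr 1 and 0.0673 without dStr 3. Drd1 and Tac1 did not differ between NAc and dStr past the test, at log2 differences of -0.38 and -0.03.

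Imprinted genes had 5 of 27 members higher in NAc and 1 lower (12 and 1 adjusted over the list alone), including Dlk1, Usp29 (2.13-fold) and Grb10 (a log2 difference of 0.80), with a mean of 0.48 (adjusted p = 4.04e-06; adjusted p = 0.156 with an estimated correlation). Neuropeptide receptor genes had 3 of 25 higher, Trhr, Adcyap1r1 and Cckbr, and none lower (7 and 0 adjusted over the list alone). Their mean was 0.42 and their median 0.11 (adjusted p = 0.00115, and 0.0794 with an estimated correlation). The other kept probe set of Adcyap1r1 and of Cckbr went the opposite way. The receptor list shares Trhr and Calcr, among others, with the ventral striatum list, and the imprinted list shares Dlk1 with it. These list results are therefore not independent. Trhr averaged 504 ± 438 in NAc, with 984 on NAc 1 and 126 on NAc 3, and its adjusted p of 0.012 became 0.0691 without dStr 1 and 0.0708 without dStr 3. Among 25 immediate early genes 4 were lower in NAc (7 adjusted over the list alone), Ier5 (2.78-fold) and, less stably, Egr2, Egr3 and Egr4, with a mean of -0.57 (adjusted p = 9.11e-05; adjusted p = 0.389 with an estimated correlation). Microglia genes had a mean of -0.27 (adjusted p = 0.00722; adjusted p = 0.535 with an estimated correlation), with 0 of 14 members passing over all genes or adjusted over the list alone. Endothelium and pericyte genes had a mean of -0.24 (adjusted p = 0.00737; adjusted p = 0.156 with an estimated correlation; 0.0713 without NAc 3), also with 0 of 17 members passing either way.

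The 291 genes became 192 without NAc 3, 134 without dStr 1, 136 without dStr 2 and 112 without dStr 3, and genes higher in NAc outnumbered lower ones without NAc 1 (232 and 187), NAc 3 (98 and 94), dStr 1 (68 and 66) and dStr 2 (70 and 66). Of 53 named calls 28 ended when any 1 array was left out, 25 of them without dStr 3, and besides Drd2 and Trhr the adjusted p without dStr 3 was 0.09 for Pdyn, 0.101 for Foxp1, 0.105 for Syndig1l, 0.15 for Egr3 and 0.176 for Cckbr, and without dStr 1 it was 0.137 for both Egr2 and Egr4.

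**Figure D3:**
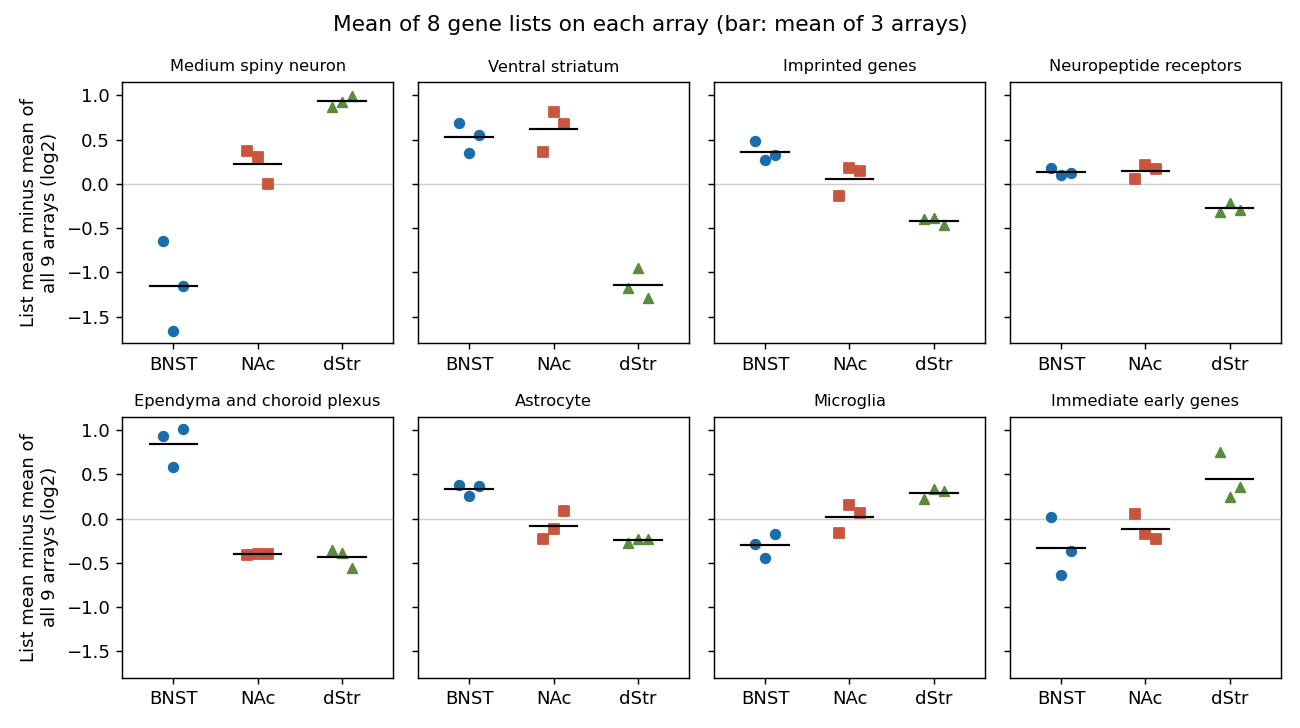
Mean of the measured members of 8 gene lists on each array, on the log2 scale relative to the mean of the 9 arrays, with points for arrays grouped by region. The medium spiny neuron list lies between -1.66 and -0.64 on the BNST arrays and between 0.87 and 1.00 on the dStr arrays, and the ependyma and choroid plexus list is above 0 on the BNST arrays alone.

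Several ependymal genes were higher and several striatal projection neuron genes lower in BNST than in NAc. Tmem212, a gene of ciliated ependymal cells, averaged 623 ± 288 (SD, n = 3 arrays) in BNST and 16.4 ± 2.51 in NAc, with 2 of the 3 NAc arrays at the floor, a log2 difference of 4.20 (SE 0.26, adjusted p = 5.6e-05). The zinc finger gene Zic1 averaged 2370 ± 329 against 322 ± 155, 7.54-fold higher in BNST, and Calb2 1260 ± 390 against 159 ± 59, 7.27-fold higher. The retinoic acid receptor gene Rarb averaged 97.9 ± 35.9 in BNST and 596 ± 185 in NAc, a log2 difference of -2.42 (SE 0.27, adjusted p = 0.002). Gpr6 was 5.13-fold lower in BNST (259 ± 130 against 1310 ± 280), and Cartpt 3.9-fold lower (306 ± 111 against 1200 ± 186).

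Between BNST and NAc 318 genes passed, 108 higher and 210 lower in BNST, of which 221 differed by at least 1 on the log2 scale (76 higher and 145 lower). The arrays did not overlap for 14.6% of genes, against an average of 10% over all splits. Genes that vary together can move this share in any 1 split, so it is not by itself an excess over chance. Genes higher in BNST included Ccdc153 (17.8-fold), Asb4 (5.15-fold), Enkur (4.95-fold), the granule-docking gene Sytl4 (4.18-fold) and the transcription factor gene Sp8 (3.85-fold). Otx2 was at least 18-fold higher, with all NAc arrays at the floor. Genes lower in BNST included Serpina9 (5.18-fold, with 2 of the 3 BNST arrays at the floor), Prkch (4.79-fold), Pcp4l1 (4.62-fold), Dclk3 (4.47-fold) and Foxp2 (4.31-fold).

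In the medium spiny neuron list 19 of 31 members were lower in BNST than in NAc and none higher (27 and 0 adjusted over the list alone), with a mean of -1.38 (camera adjusted p = 3.78e-28; adjusted p = 0.123 with an estimated correlation). Tac1 (3.53-fold), Gng7 (3.24-fold) and Gpr6 were among them, as was Drd1, whose adjusted p of 0.017 became 0.0772 without BNST 3 and 0.0837 without NAc 2. Of 44 metabotropic and cyclic nucleotide signalling genes 11 were lower, including Rgs8 (2.88-fold), and none higher (22 and 2 adjusted over the list alone), with a mean of -0.66 (adjusted p = 7.36e-11; adjusted p = 0.18 with an estimated correlation). Relative to the mean of the 9 arrays this list stood at -0.18 on BNST 1, -0.75 on BNST 2 and -0.53 on BNST 3, and its mean difference was -0.62 with the housekeeping covariate (adjusted p = 3.46e-10). Voltage-gated potassium channel genes had 7 of 30 lower and none higher (12 and 0 adjusted over the list alone), with a mean of -0.49 (adjusted p = 1.44e-06; adjusted p = 0.163 with an estimated correlation). BNST 1 was at -0.11, BNST 2 at -0.57 and BNST 3 at -0.35 for this list, and the covariate gave a mean difference of -0.45 (adjusted p = 1.29e-05). Dopamine and monoamine receptor genes had Drd1 and Drd2 lower and Htr7 higher among 17 (5 and 1 adjusted over the list alone), with a mean of -0.39 (adjusted p = 0.0305; adjusted p = 0.279 with an estimated correlation). The adjusted p of that list was 0.071 without BNST 1 and 0.26 without NAc 1.

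The ependyma and choroid plexus list had 7 of 16 members higher in BNST than in NAc and none lower, over all genes and adjusted over the list alone. They were Tmem212, Ccdc153, Otx2, Enkur, Dynlrb2 (4.35-fold), Ak7 and Rsph1, and the list's mean was 1.25 and its median 0.40 (adjusted p = 3.88e-14, and 0.0312 with an estimated correlation). The astrocyte list was the only other list past the threshold with an estimated correlation in this comparison. It had 3 of 22 members higher, Gfap (3.33-fold), Mlc1 and Sox9, and none lower (7 and 0 adjusted over the list alone), with a mean of 0.42 (adjusted p = 1.07e-09, and 0.0312 with an estimated correlation). Microglia genes had a mean of -0.32 with 0 of 14 members passing over all genes or adjusted over the list alone (adjusted p = 0.00187; adjusted p = 0.276 with an estimated correlation). Oligodendrocyte precursor genes had a mean of 0.16, again with 0 of 11 members passing either way (adjusted p = 0.0239; adjusted p = 0.276 with an estimated correlation; 0.0604 without BNST 1 and 0.215 without NAc 1).

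Neuropeptide and hormone genes went both ways between BNST and NAc. Tac2 (3.77-fold), Pnoc (2.61-fold), Ecel1 (2.41-fold) and Crh were higher in BNST, and Cartpt, Tac1 and Pdyn (2.22-fold) lower, or 5 and 4 of 32 adjusted over the list alone, with a mean of 0.14 (adjusted p = 0.00934; adjusted p = 0.32 with an estimated correlation). With unsuffixed probe sets alone the mean was 0.06 and the call ended (adjusted p = 0.114). Imprinted genes had 5 of 27 higher and none lower (7 and 2 adjusted over the list alone), including Asb4, Magel2 (3.61-fold) and Grb10 (a log2 difference of 0.69), with a mean of 0.30 (adjusted p = 2.3e-05; adjusted p = 0.163 with an estimated correlation). Plagl1 was 2.8-fold higher, with its other kept probe set going the opposite way. The preoptic, hypothalamic and septal patterning list had Zic1, Zic4 (2.79-fold) and Zic5 (2.05-fold) higher and Tshz1 lower among 22 (4 and 1 adjusted over the list alone). Its mean was 0.23 and its median 0.06 (adjusted p = 0.0139, and 0.18 with an estimated correlation). That call ended with no filter (mean 0.13, adjusted p = 0.128) and with BNST 1 and NAc 1 left out together (mean 0.09, adjusted p = 0.155). The thalamus and habenula list had Calb2, Tac2, Slc17a6 (3.54-fold) and Prkcd (2.29-fold) higher and Ramp3 lower among 18 (5 and 1 adjusted over the list alone). Its mean was 0.44 and its median 0.14 (adjusted p = 7.91e-05, and 0.086 with an estimated correlation). The GABAergic neuron list had Calb2 and Dlx1 higher and none lower among 15 (3 and 0 adjusted over the list alone). Its mean was 0.37 and its median 0.04 (adjusted p = 0.0167, 0.276 with an estimated correlation, 0.0766 without BNST 1 and 0.0742 without NAc 1).

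The 318 genes became 617 without BNST 1, 145 without BNST 2, 101 without BNST 3, 112 without NAc 2, 483 without NAc 3, 175 without dStr 1, 194 without dStr 2 and 189 without dStr 3. Leaving out a dStr array does not change the differences between BNST and NAc. Those counts fell through the shared spread and its degrees of freedom, so many of the 318 calls rest on the dStr arrays. The excess of lower genes was not stable. It shrank to 200 higher and 235 lower (46% higher, from 34%) under quantile normalisation. It turned over with 78 higher and 67 lower without BNST 2, 53 and 48 without BNST 3, 63 and 49 without NAc 2, and 43 and 28 with only the 6 arrays of the pair. It grew to 129 higher and 488 lower without BNST 1, 150 and 333 without NAc 3, and 349 and 1854 without both BNST 1 and NAc 1. Of 69 named calls 31 ended when any 1 array was left out, 28 of them without BNST 3 and 26 without NAc 2, and besides Drd1 the highest adjusted p was 0.0545 for Ramp3, 0.066 for Drd2, 0.0955 for Mlc1, 0.154 for Sox9 and 0.166 for Htr7 without BNST 3, 0.128 for Crh without BNST 2, and 0.125 for Dlx1 and 0.178 for Tshz1 without NAc 2.

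Against both other regions, 106 genes were highest in BNST, 9 in NAc and 149 in dStr. If the paired comparisons were independent, 5.3, 2 and 14.5 genes would pass both. In 20 simulations with no difference in any gene the count was 0. With no difference hardly any gene passes even 1 comparison, so these simulations do not measure the overlap that shared arrays give. Part of the excess may come from the arrays that both comparisons share, since 3 arrays cannot be parted into sets of at least 2 each. The genes highest in BNST included Tmem212, Ccdc153, Otx2, Zic1, Calb2, Asb4, Enkur, Fam183b and Lbhd2. Those highest in NAc were Cartpt, Pdyn, Stard5, Wfs1, Ramp3, Slco5a1, Perp, Ttc39c and Lin7a. Of these 9, Cartpt alone kept both calls whichever array was left out. The highest adjusted p was 0.09 for Pdyn, 0.0587 for Ramp3 and 0.113 for Slco5a1 against dStr without dStr 3, 0.181 for Perp against dStr without dStr 1, 0.159 for Wfs1 against BNST without NAc 2, and 0.0985 for Stard5, 0.0733 for Ttc39c and 0.155 for Lin7a against BNST without BNST 2. Those highest in dStr included Coch, Rasgrp2, Fgf20, Abhd11os, Plxnd1, Fam241a and Slc44a4. The lowest level was in BNST for 187 genes, in NAc for 2 and in dStr for 111, against 19.6, 1.2 and 6.7 if independent.

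The number highest in BNST was 52 without BNST 3, 63 without NAc 2, 69 without dStr 1 and 70 without dStr 3. The number highest in NAc was 19 without BNST 1, 5 without BNST 2, 3 without BNST 3, 2 without NAc 2, 17 without NAc 3, 3 without dStr 1, 2 without dStr 2 and 2 without dStr 3. The number highest in dStr was 227 without BNST 1, 98 without BNST 3, 89 without NAc 3, 62 without dStr 1, 64 without dStr 2 and 55 without dStr 3.

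Some lists held members that moved apart and did not pass as a whole in the main analysis, although 1 of them passed with some of the alternatives. Of 22 striatal patterning genes 8 were lower and 4 higher in BNST than in dStr (10 and 4 adjusted over the list alone), with Rarb (7.11-fold) and Foxp1 (6.54-fold) lower, Dlx1 at least 17.9-fold and Sp8 at least 7.59-fold higher, and a list mean of -0.50 (adjusted p = 0.112, but 0.033 with quantile normalisation and 0.0101 with a filter at the 60th percentile). Against NAc 8 were lower and 3 higher in BNST (9 and 4 adjusted over the list alone), with an adjusted p of 0.0611, which was 0.0118 with quantile normalisation, 0.0406 with centring, 0.00347 with a filter at the 60th percentile and 0.041 with unsuffixed probe sets. Between NAc and dStr 2 were lower (adjusted p = 0.609). Of 28 ionotropic receptor genes 7 were lower and 6 higher in BNST than in dStr (10 and 8 adjusted over the list alone; adjusted p = 0.662). The GABA-A receptor genes Gabrd (5.88-fold) and Gabra4 (3.91-fold) were lower there, and Gabrg1 (3.53-fold), the glycine receptor gene Glra2 (2.8-fold) and the NMDA receptor gene Grin3a (3.16-fold) higher. That list gave adjusted p values of 0.848 between BNST and NAc and 0.795 between NAc and dStr. The ventral striatum list did not pass between BNST and NAc, with 3 members higher and 4 lower in BNST (3 and 6 adjusted over the list alone; adjusted p = 0.58).

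For the lists that passed in no comparison, the adjusted p values are given in the order BNST against NAc, BNST against dStr and NAc against dStr. They were 0.0548, 0.303 and 0.822 for sex steroid and corticosteroid signalling, in which Sytl4 was 4.36-fold higher in BNST than in dStr (2 of the 3 dStr arrays at the floor), and 0.704, 0.616 and 0.609 for glutamatergic and cortical projection neurons. They were 0.289, 0.292 and 0.609 for cholinergic neurons, 0.0568, 0.905 and 0.185 for oligodendrocytes and myelin, 0.541, 0.797 and 0.872 for blood, and 0.0592, 0.537 and 0.609 for stress and heat shock genes. Between BNST and NAc the sex steroid list passed without BNST 2 (0.0479), BNST 3 (0.0341) or NAc 1 (0.0441), and the stress list without BNST 2 (0.0106), BNST 3 (0.0341) or NAc 3 (0.0306). The oligodendrocyte list passed there without BNST 3 (0.0101) or NAc 3 (0.000205), and between NAc and dStr without NAc 3 (0.000809), and the striatal patterning list passed between BNST and NAc without BNST 2 (0.0484). Mean, median and test differed in sign for none of the lists that passed. They differed for the neuropeptide receptor, glutamatergic, cholinergic, ionotropic receptor, endothelium and blood lists between BNST and NAc, for the GABAergic, glutamatergic, ionotropic receptor, oligodendrocyte, blood and stress lists between BNST and dStr, and for the preoptic and ionotropic receptor lists between NAc and dStr.

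The lists that passed in some comparisons gave these results in the others. Between BNST and NAc, neuropeptide receptors had an adjusted p of 0.0849, endothelium and pericyte 0.848 and immediate early genes 0.251. Between BNST and dStr, the preoptic list had 0.116 (0.0476 without dStr 1), the GABAergic list 0.113, monoamine receptors 0.196, oligodendrocyte precursors 0.162 and endothelium and pericyte 0.0799 (0.0287 without BNST 2 and 0.0299 without dStr 1). Between NAc and dStr, neuropeptides had 0.1 (0.00827 without dStr 2), the preoptic list 0.915, the GABAergic list 0.609, thalamus and habenula 0.293, monoamine receptors 0.815, cyclic nucleotide signalling 0.431, potassium channels 0.609, oligodendrocyte precursors 0.822, astrocytes 0.163, and ependyma and choroid plexus 0.74.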

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

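The housekeeping covariate, leaving out BNST 1 and NAc 1 together, and the restriction to unsuffixed probe sets were chosen after seeing the data. Leaving out 1 array at a time gave 101 to 617 genes between BNST and NAc, 1112 to 2674 between BNST and dStr, 112 to 419 between NAc and dStr and 740 to 1962 among the 3 regions, 52 to 140 highest in BNST, 2 to 19 in NAc and 55 to 227 in dStr, and 10 to 16, 12 to 14 and 7 to 8 lists. Fewer arrays and a changed spread accompany these values. Leaving out an array of the region outside a pair alters only the shared spread and its degrees of freedom, not the differences of that pair. For the other arrays the cause was not tested. Quantile normalisation gave 188 genes highest in BNST and 14 in NAc, and centring 14 in NAc. A minimum log2 difference of 1 gave by construction fewer genes, 866 between BNST and dStr, 175 between NAc and dStr, 844 among the regions, and 70, 4 and 97 highest in BNST, NAc and dStr. With only the 6 arrays of the pair 71 genes passed between BNST and NAc, all 71 among the 318. An estimated correlation left 2, 0 and 1 lists. The replicate block gave 196 genes between BNST and NAc, 183 between NAc and dStr, 953 among the regions and 68, 5 and 92 highest in BNST, NAc and dStr, and it let the oligodendrocyte (0.05) and stress (0.0491) lists pass between BNST and NAc. Whether equal numbers pair the samples is not known. Of 9 pairs with 1 number, residual r ran from -0.51 to 0.26, with 2 over 0.1. These values show no pairing but cannot rule it out, since the lowest is that of BNST 1 and NAc 1, which stood apart from their regions. The housekeeping covariate gave 549 genes between BNST and NAc, 511 between NAc and dStr and 208, 18 and 245 highest in BNST, NAc and dStr. Without BNST 1 and NAc 1 the counts were 2203, 4150, 707 and 3686 for the comparisons and the 3 regions, and 316, 74 and 326 highest. The cause was not tested for the scalings, the covariate or the pair left out. Of the single genes 4852 values kept direction and call, 572 kept direction and lost the call, and 5 reversed. Kcnc4 between BNST and dStr was -0.26 with a pseudocount of 1 and -0.23 with unsuffixed probe sets, Synpo2 was 0.13 between BNST and dStr and 0.20 between NAc and dStr with a pseudocount of 1, and Plagl1 between BNST and NAc was -0.06 with unsuffixed probe sets. These settings can pick another probe set of the gene. Of the list values 1496 were unchanged in call, 33 passed anew, 46 lost the call and 0 reversed. Besides the calls that ended with an estimated correlation or without 1 array, and those of the preoptic, neuropeptide and striatal patterning lists given with them, calls ended between BNST and NAc for monoamine receptors (0.0513 with the 60th percentile filter and 0.366 without BNST 1 and NAc 1), oligodendrocyte precursors (0.0513, 0.3 without that pair and 0.0522 with unsuffixed probe sets) and the GABAergic list (0.283 without that pair), and between NAc and dStr for endothelium (0.0604 with that filter). Lists passed anew between BNST and NAc for oligodendrocytes (0.0399 with quantile normalisation and 0.0145 with the covariate), cholinergic neurons (0.037 with the 60th percentile filter), sex steroids (0.0456 with a pseudocount of 1) and stress (0.026 with the covariate). Between BNST and dStr they did for endothelium (0.00687 with no filter and 0.0268 with the covariate), the preoptic list (0.0187 with the mean of probe sets) and the GABAergic list (0.0403 with the covariate), and between NAc and dStr for neuropeptides (0.0335 with the 60th percentile filter) and thalamus and habenula (0.0276 with a pseudocount of 1). The list tests were not run with the trend and robust prior. Signal over the floor limits genes dim in 1 region, whose folds the pseudocount shrinks.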

Other observations

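The tests of a label exchange, of choroid plexus tissue and of the projection neuron pathways, the single-array picks in the mixture test, the count against the median change of the medium spiny neuron list and the splits with dStr kept whole were chosen only after the results were seen.

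Some genes of motile cilia outside the fixed lists were higher in BNST. Of 33 measured, 7 passed as higher against NAc and 10 against dStr, and 0 passed as lower. Rsph9, a radial spoke gene, had log2 differences of 0.87 (SE 0.15, adjusted p = 0.018) against NAc and 1.87 (SE 0.15, adjusted p = 8.8e-05) against dStr. Cfap54 had 1.30 and 1.77, Rsph4a 1.13 and 1.82, and Tppp3 1.29 and 1.11. Of 5470 kept probe sets without 1 gene symbol, 44 passed between BNST and NAc, 576 between BNST and dStr and 37 between NAc and dStr. Over the 9 arrays Xist ranged from 77.7 to 117, Eif2s3y from 189 to 430, Kdm5d from 57.7 to 104 and Uty from 57.2 to 102.

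BNST 1 and NAc 3 differed from BNST 2, BNST 3 and NAc 1 in a way that the regions do not give. The 116 ribosomal protein and respiratory chain genes had a median difference of 0.61 between NAc 3 and NAc 1 and 0.26 between BNST 1 and the mean of BNST 2 and BNST 3. Both lay above all 10000 random lists (largest 0.16 and 0.24). These lists were matched on mean expression alone, and a co-regulated set may exceed them. The mean of the 116 genes was 10.7 on BNST 1, 10.1 on BNST 2 and 10.6 on BNST 3, so in BNST the low array was BNST 2. A difference in RNA yield or labelling stays open. An exchange of the labels of BNST 1 and NAc 1 is argued against, since on 128 genes higher in BNST, with NAc at 0 and BNST at 1, NAc 1 stood at 0.22 and BNST 1 at 0.78, and Otx2 read 372 on BNST 1 and 15 on NAc 1. Other values go partly with an exchange: on 538 genes higher in NAc the order turned over, with BNST 1 at 0.33 and NAc 1 at 0.43. A full exchange would put NAc 1 near 1 and BNST 1 near 0, and NAc 1 stayed nearer to NAc. Exchanged labels gave 1746 genes against 318. With the housekeeping covariate it was 0 against 549, which cannot decide the question. The covariate itself parted the exchanged groups, at 10.081 to 10.559 with NAc 1, BNST 2 and BNST 3 and 10.584 to 10.857 with BNST 1, NAc 2 and NAc 3. More striatal tissue in BNST 1 cannot be told apart from no admixture: a fitted dStr share of 13.2% predicted a median change of -0.12 in BNST genes and -0.075 was observed (-0.134 to -0.029), but genes picked on BNST 2 alone gave -0.17 against -0.13 predicted, and genes picked on BNST 3 alone 0.04 against -0.11. The bracketed range comes from resampling genes, not arrays. Of the 28 medium spiny neuron genes used for the fit, 25 were higher on BNST 1 than on BNST 2 and BNST 3. Admixture of NAc tissue was not tested. No biological explanation of the spread within a region was tested.

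The ependyma and choroid plexus list was higher in BNST than in both other regions. With an estimated correlation it passed camera against NAc (adjusted p = 0.0312) but not against dStr (adjusted p = 0.0662). Choroid plexus tissue as the source of the whole list is argued against by 9 measured genes, with a median difference of 0.12 (-0.09 to 0.40) against NAc and 0.13 (-0.07 to 0.28) against dStr, and by Ttr, at 0.40 (adjusted p = 0.58) and 0.39 (adjusted p = 0.32), with 621 on BNST 1 and 271 to 340 on the other arrays. The bracketed ranges come from resampling the 9 genes, not the arrays, so they hold no spread between samples. Otx2, 1 of the 9 and also a choroid plexus gene, goes the other way, with 372 on BNST 1, 209 on BNST 2, 250 on BNST 3 and 15 on every NAc and dStr array, so its source, and some choroid plexus in BNST 1, stay open. Cells lining the ventricle in the BNST punches may contribute, since the motile cilia genes passed camera with an estimated correlation (p = 0.0058 against NAc and 0.016 against dStr). A difference between the regions themselves stays open and was not tested.

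The medium spiny neuron list was lower in BNST and in NAc than in dStr. With an estimated correlation neither difference passed camera (adjusted p = 0.133 and 0.532). An equal log2 change of all members is argued against by the number that differed from the median change of the list. Between BNST and dStr (-2.13) 6 of 31 fell less or rose and 5 fell more. Between NAc and dStr (-0.72) 3 fell less or rose, Pdyn (0.98), Isl1 (0.36) and Meis2 (-0.02), and 4 fell more. Setting members against their own median favours differences on both sides, so that balance carries no weight. With the list median taken on each array, which itself differed by -2.51 and -0.82, 13 members differed (11 and 2) and 8 (5 and 3). A single lower share of these neurons need not change all members equally, since the pseudocount shrinks changes of dim genes and other cells may express some members. Such a share therefore stays open. A yield or labelling difference as the whole cause is argued against by list means of -2 between BNST and dStr and -0.67 between NAc and dStr with the housekeeping covariate, from -2.08 and -0.71. A difference between the kinds of projection neuron may contribute in NAc against dStr, where 5 indirect pathway genes had a mean of -0.55 and 7 direct pathway genes 0.12, but Drd2 and Pdyn, which prompted the test, carried about as much of the difference of -0.67 as the others: without them it was -0.33, with NAc arrays from 0.22 to 0.38 and dStr arrays from 0.48 to 0.90 (for all members, exact 2-sided permutation p = 0.1, the smallest that 3 against 3 allow). Regional differences in expression within these neurons stay open and were not tested.

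Other groupings of the arrays were fitted. With 10 splits of 6 arrays a share under 0.05 could not be reached: 2 splits gave as many genes as BNST against NAc (318, highest other 1746), 1 as BNST against dStr (2027, highest other 0) and 1 as NAc against dStr (291, highest other 1). For lists it was 1 split each, with 13, 12 and 7 and highest others of 6, 10 and 6. Among 100 groupings of the 9 arrays 3 gave as many genes differing among the regions (1461), 2 as many highest in BNST (106, highest other 204), 3 in NAc (9, highest other 104) and 2 in dStr (149, highest other 156). These shares are under 0.05, but most of these groupings break up dStr. They show at most that dStr stands apart and say little on BNST against NAc. For the count among the regions chance is therefore not excluded. With dStr kept whole, 2 of 20 splits gave as many highest in BNST and 4 as many in NAc (highest other 156 for both), so for these counts chance is not excluded. The highest other count among the regions, 3027, came from a grouping that kept dStr whole, put BNST 1 with NAc 2 and NAc 3, and put NAc 1 with BNST 2 and BNST 3, which points to a structure of the samples besides the region.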
